A study of Mus musculus with 94 samples.

How the data were processed

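RNA was measured with the GeoMx Digital Spatial Profiler, an instrument on which tissue sections are hybridised with probes that carry cleavable index oligonucleotides, and ultraviolet light releases those oligonucleotides from chosen areas for sequencing. Per the labels' protocols, sections of formalin-fixed, paraffin-embedded mouse brain were incubated with the mouse Whole Transcriptome Atlas probes. They were stained for OLIG2, a transcription factor of the oligodendrocyte lineage. Separate stains were a D54D2 antibody, which is not the OLIG2 stain, and a DNA dye. Regions were segmented on the OLIG2 stain to give areas of interest (AOIs), so OLIG2 itself was used to choose the areas. The brain regions from which the areas were taken, and the rule by which regions were chosen, are not given in the sources used here. Of the 95 AOIs that the protocol counts, 94 were analysed and 1 was not analysed here.

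The deposited values are whole-number counts per probe and AOI. Per the file headers, reads were trimmed, stitched with an overlap of 25 to 32 bases and aligned to the probes' 12-base tags with up to 1 edit by DRAGEN_GeoMx version 3.8.4-96. Reads with the same 14-base molecular identifier, allowing 1 edit, were counted once, per the file headers, so that each count stands for 1 molecule. The submitters' processing notes name the genome build mm10, and no coordinates were used here. No background subtraction, scaling or probe filter is recorded in the headers, and the counts were treated as raw. All AOIs belonged to 1 plate and 1 sequencing set. WT AOIs lay in plate rows A to D and 5XFAD AOIs in rows E to H, each animal in consecutive wells. Position on the plate therefore cannot be told apart from genotype or animal. The library names carry 1 stem per genotype, so any slide or run difference between the genotypes cannot be told apart from genotype.

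The files identify probes by tag identifier only. None of the 20175 identifiers (0 matched) was found in the gene table used here, which is of assembly GRCm38.p6, so no probe was given a gene name. The planned tests of gene lists, the planned named genes, the cell type markers and the planned filter against negative control probes were therefore not run. At most 2 probes that rose and 2 that fell are printed by identifier.

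The replicate was the animal, as numbered in the sample descriptions, and not the AOI. Counts of the AOIs of an animal were summed, which weights an animal's profile towards its deepest AOIs. The sums of 3 wild-type and 3 5XFAD animals were compared with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test, with TMM scaling, the filterByExpr filter by genotype and genotype as the only term. The filter removed 1 probe and left 20174. Probes with a Benjamini-Hochberg adjusted p under 0.05 are called, and fold changes are 5XFAD over WT. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Normalized levels are given as CPM with TMM factors. The probes to be named were fixed before the data were examined as the 2 largest rises and 2 largest falls by fold change among called probes whose 3 animals of one genotype all lay above the 3 of the other.

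Depth per animal was the mean over AOIs of the log10 total count. Sequencing saturation was 1 minus deduplicated over aligned reads, as a percent, averaged over AOIs. The spread between AOIs was the median, over the 1000 probes of highest mean CPM, of the SD over an animal's AOIs of log2(CPM + 1), after each AOI was thinned at random to 103170 counts. That total was the lowest among AOIs with at least 1/3 of the median total, and the 8 shallower AOIs (2 WT, 6 5XFAD) were left out of the spread. These 3 quantities were compared by two-sided exact permutation tests of the difference of means, for which 3 against 3 animals allow no p below 0.1.

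Other settings, chosen before the data were examined, were DESeq2 1.42.0, upper-quartile scaling, library size alone, no filter, a filter to the upper part of the probes by mean CPM, the mean of AOI log2 values per animal in limma 3.58.1, AOIs in limma voom with the animal as a random block, thinned AOIs, removal of shallow AOIs, removal of AOIs with a saturation under 50%, the animal number as a block, and each animal left out in turn. The removal of WT AOI 17, of WT AOIs 33 and 34, and of these 3 together, and that of the AOI of low saturation from the saturation difference, was added after seeing the data. The edgeR steps were tested on simulated data for 5XFAD against WT, in which counts for 20174 probes were drawn from the real means, library sizes and dispersions and 200 probes were changed. In this simulation 6 of 67 probes changed by 1.5-fold, 30 of 67 changed by 2-fold and 60 of 66 changed by 4-fold were called. Of the 106 calls in all, 10 fell among the 19974 unchanged probes. Simulated probes were drawn independently, with the same dispersion in both genotypes. The real WT animals varied more than the 5XFAD animals and their probes shifted together, so these rates need not hold for the data.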

Results

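Transcripts were counted in OLIG2-segmented areas of brain from 6-month-old female mice of 2 genotypes. Wild-type (WT) animals were of the Black6 strain, and 5XFAD animals are a transgenic model of Alzheimer's disease that forms amyloid plaques. The series concerns STING signalling, a response to DNA in the cytosol, in oligodendrocytes in Alzheimer's disease. Each genotype was represented by 3 animals. The 46 WT AOIs came from animals 1, 2 and 3 in numbers of 17, 17 and 12, and the 48 5XFAD AOIs were 16 per animal. In all, 62769332 deduplicated counts were recorded for 20175 probes, of which 5718 were seen in every AOI. Probes were identified by tag and not by gene, so that the comparisons below concern probes.

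Depth varied more between AOIs than between genotypes. Totals per AOI ran from 25606 to 7912242 counts, a 309-fold range, with a median of 294012. Summed over AOIs, WT animals 1, 2 and 3 held 6937751, 34248943 and 6277527 counts, and 5XFAD animals 1, 2 and 3 held 5374455, 3223819 and 6706837. A single AOI supplied 38.4% of the counts of WT animal 1, and the largest AOI of the other animals supplied between 14.9% and 26.5%. The mean log10 total per AOI was 5.71 ± 0.39 (SD, n = 3) in WT and 5.35 ± 0.13 (SD, n = 3) in 5XFAD. This difference, -0.363, was within the spread between animals (two-sided exact permutation p = 0.3, smallest possible 0.1), and it was -0.158 without WT animal 2.

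**Figure D1:**
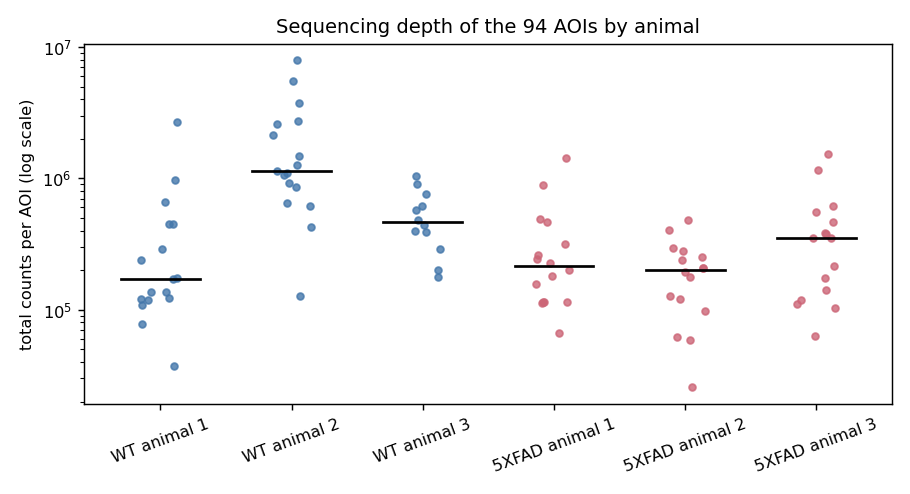
Total deduplicated counts of each of the 94 AOIs (log axis), by animal; each point is an AOI and each bar the median of an animal. WT animal 2 has the highest median and the deepest AOI, 7912242 counts.

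Sequencing saturation was 86.1% ± 0.54 (SD, n = 3) in WT and 84.8% ± 2.28 (SD, n = 3) in 5XFAD. The difference of -1.30 percentage points was not separable from the spread between animals (two-sided exact permutation p = 0.5, smallest possible 0.1). In 5XFAD animal 1, 1 AOI had a saturation of 32.2%, and all other AOIs of the 6 animals lay between 78.0% and 89.6%. Without this AOI the difference was -0.186 points, without 5XFAD animal 1 it was -0.0776 points, and with medians over AOIs it was 0.355 points, in the opposite direction.

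To ask which transcripts differed in OLIG2-segmented areas between the genotypes, the counts of each animal were summed and compared. Of 20174 probes tested, 2197 differed between 5XFAD and WT (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 3 and 3 animals). Of these, 1883 were lower and 314 were higher in 5XFAD, so that 14.3% of the called probes were higher. The lower probes had a median log2 fold change of -1.48 (quartiles -1.91 and -1.20), and 1703 of them were at least 2-fold lower. Among the higher probes the median was 0.88 (quartiles 0.78 and 1.05), with 99 at least 2-fold higher. At least 4-fold differences were found for 412 lower and 12 higher probes. An unadjusted edgeR p under 0.05 was reached by 7075 probes, where 1008.7 would be reached by chance on average. Since probes shift together between animals, the number reached by chance can lie far from this average. The smallest adjusted p was 0.0214. The called higher probes had a median level of 29.4 CPM, below the 38.8 CPM of all tested probes. The 1st percentile of probe CPM before TMM scaling was 16.75 to 19.54 in the 5XFAD animals. It was 10.88 and 10.67 in WT animals 2 and 3 and 16.86 in WT animal 1. No filter against negative control probes was run, so small rises were not told apart from higher background.

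These calls depended on single animals and on 1 AOI. The edgeR test called 11336 probes without WT animal 1, 553 without WT animal 2 and 0 without WT animal 3 or without any 1 of the 5XFAD animals; in those 4 cases between 4039 and 5213 probes had an unadjusted p under 0.05 and DESeq2 called between 2566 and 3620. Without AOI 17 of WT animal 1, a removal chosen after seeing the data, edgeR called 0 probes, with 5405 at an unadjusted p under 0.05 and 3883 called by DESeq2; without AOIs 33 and 34 it called 2083.

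The size of the count also depended on the test and the scaling. DESeq2 called 5946 probes, 30.4% of them higher in 5XFAD, edgeR with upper-quartile scaling 1029 and edgeR with library size alone 1268. Lower probes outnumbered higher ones in each setting that called any, by more or by less. Higher probes made up 5.61% of the 553 calls without WT animal 2 (31 higher and 522 lower). Their share was 49.7% of the 7698 calls with AOIs in limma voom and the animal as a random block, 46.3% of those without WT animal 1 and 45.3% of the 7127 calls with the animal number as a block. The limma voom setting took AOIs as observations, with 1 intra-animal correlation of 0.20 for all probes. Its count can therefore overstate what the few animals bear out. Whether the shared animal numbers pair the animals was not settled by the data. Over all probes the median log2 fold change was 0.05 with TMM scaling, 0.26 with upper-quartile scaling and 0.20 with library size alone, and fold changes are given relative to the TMM scale.

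The 2 largest rises in 5XFAD among called probes whose animals did not overlap were those of RTS0064820 and RTS0064807. RTS0064820 was at 345 ± 65.6 CPM (SD, n = 3) in 5XFAD and at 36.1 ± 12.7 CPM (SD, n = 3) in WT, a 9.56-fold difference (log2 fold change 3.26, SE 0.47, edgeR adjusted p = 0.0214). RTS0064807 was at 1020.4 ± 131.6 CPM (SD, n = 3) in 5XFAD and 115.7 ± 47.7 CPM (SD, n = 3) in WT, 8.83-fold higher (log2 fold change 3.14, SE 0.64, edgeR adjusted p = 0.0229). Both were more even within each genotype than the 2 probes that fell most. The largest fall was that of RTS0067798, at 40.1 ± 9.37 CPM (SD, n = 3) in 5XFAD and 854 ± 545 CPM (SD, n = 3) in WT, 21.3-fold lower (log2 fold change -4.41, SE 0.76, edgeR adjusted p = 0.0214). RTS0064241 followed, at 169.7 ± 71.2 CPM (SD, n = 3) in 5XFAD and 3426 ± 2390.4 CPM (SD, n = 3) in WT, 20.2-fold lower (log2 fold change -4.34, SE 1.07, edgeR adjusted p = 0.0332). WT animal 1 stood nearest to 5XFAD for all 4 probes, with 48.7 CPM of RTS0064820 against 23.3 and 36.4 in WT animals 2 and 3, 151.0 CPM of RTS0064807 against 61.4 and 134.5, 240.9 CPM of RTS0067798 against 1282 and 1039.9, and 974 CPM of RTS0064241 against 3554 and 5749. Over all alternatives the log2 fold changes lay between 3.02 and 3.49 for RTS0064820, 2.84 and 3.34 for RTS0064807, -4.91 and -3.50 for RTS0067798, and -4.83 and -3.62 for RTS0064241. Without WT AOI 17 they were 3.21, 3.09, -4.36 and -4.28. All 4 probes lost their call, though not their direction, wherever edgeR called no probe, and RTS0064241 also lost it with upper-quartile scaling and with library size alone.

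**Figure D2:**
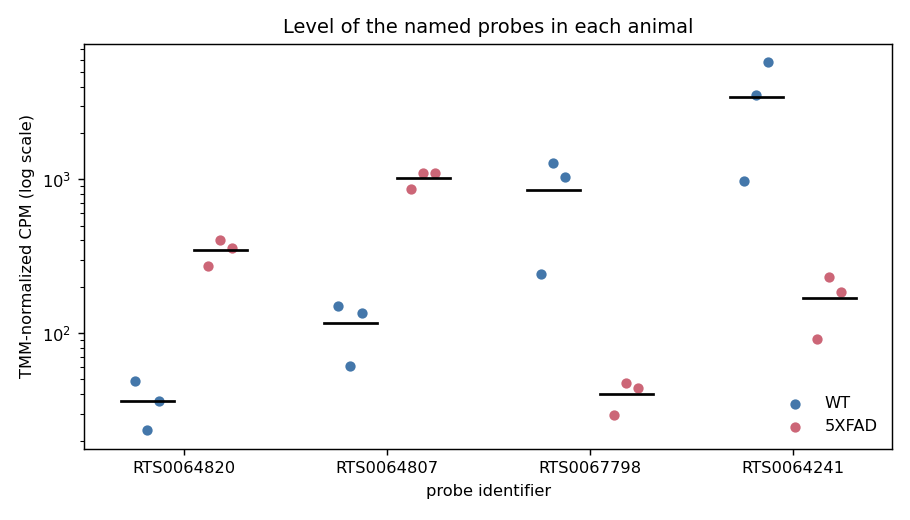
TMM-normalized CPM (log axis) of the 4 named probes; points are animals (3 per genotype) and bars the genotype means. WT and 5XFAD animals do not overlap for any of the 4, and WT animal 1, the leftmost WT point of each set, is nearest to 5XFAD for each of them.

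Calls were more frequent among probes of high mean CPM over both genotypes. This ranking is not independent of the calls, since a high level in WT alone raises a probe's mean. Of the 100 probes with the highest mean CPM, 29 were lower, 3 were higher and 68 were not called. Of the next 900 probes, 272 were lower and 12 were higher. The median log2 fold change over all probes of these 2 classes, called or not, was 0.29 and 0.09, opposite in sign to most of the calls. Of the 10174 probes ranked below 10000, 226 were lower and 215 were higher. Probes of high mean CPM also varied more between WT animals. The ranking partly builds this in, since very high levels in some WT animals raise the mean. The median SD of log2(CPM + 1) over the 3 WT animals was 1.05 for the 100 most abundant probes, against 0.27 over the 3 5XFAD animals. For probes ranked below 10000 the values were 0.27 in WT and 0.16 in 5XFAD. No single probe dominated an AOI, the highest share of any probe in any AOI being 1.19% of its counts.

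The WT animals did not share the called differences equally. The called lower probes lay at a median of 1.82 log2 units above the 5XFAD mean in WT animal 2 and 1.67 above it in WT animal 3, but only 0.55 above it in WT animal 1. For the called higher probes the medians were -1.17, -0.99 and -0.52 in the same order. Over all tested probes, 7701 (38.2%) had all animals of one genotype above all of the other, where chance gives 10% on average. Probes shift together between animals, so the share can lie far from 10% by chance. Of the 2197 called probes, 2123 were among the 7701.

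Correlations across probes between the summed animals, for which probes are not independent replicates, ordered the animals differently from genotype. WT animal 1 had Spearman correlations of 0.79 to 0.87 with the 5XFAD animals, 0.75 with WT animal 3 and 0.51 with WT animal 2. The 5XFAD animals correlated with each other at 0.81 to 0.93. WT animal 2 correlated with WT animal 3 at 0.86 and with the 5XFAD animals at 0.18 to 0.30, and WT animal 3 correlated with the 5XFAD animals at 0.45 to 0.56.

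**Figure D3:**
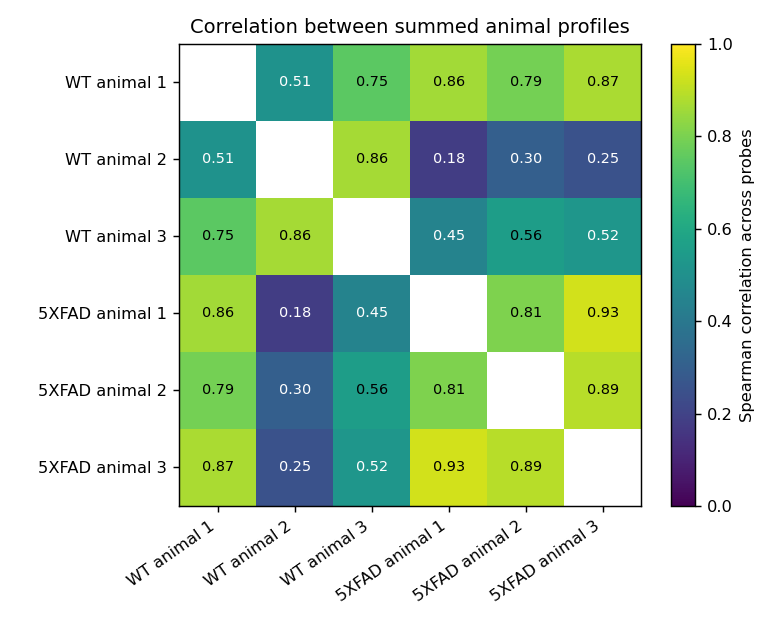
Spearman correlation across probes (colour scale 0 to 1, values printed) between the TMM-normalized profiles of the 6 animals. WT animal 1 correlates at 0.79 to 0.87 with 5XFAD animals, above its 0.51 with WT animal 2.

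Single AOIs were set against the mean profile of each animal over the 3000 probes of highest mean log level, leaving the AOI out of its own animal. All 48 5XFAD AOIs matched a 5XFAD animal best, 28 of them their own animal. Of the 46 WT AOIs, 40 matched their labelled animal best among all 6 animals and 41 among the 3 WT animals. The AOI that made the difference, AOI 9 of WT animal 1, correlated with 5XFAD animal 3 at 0.729 and with its own animal at 0.725. AOI 17, the last AOI of WT animal 1, had a Pearson correlation across probes of 0.22 with that animal and 0.93 with WT animal 2, whereas the other AOIs of WT animal 1 correlated with their animal at 0.51 or more. AOIs 27, 32, 33 and 34 of WT animal 2 matched WT animal 3 best. They correlated with WT animal 3 at 0.87, 0.89, 0.94 and 0.83 and with their own animal at 0.81, 0.80, 0.90 and 0.78, in that order. AOI 17 held 971795 of the 6937751 counts of WT animal 1, and without AOIs 17, 33 and 34 the called lower probes lay at a median of 0.30 above the 5XFAD mean in WT animal 1.

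**Figure D4:**
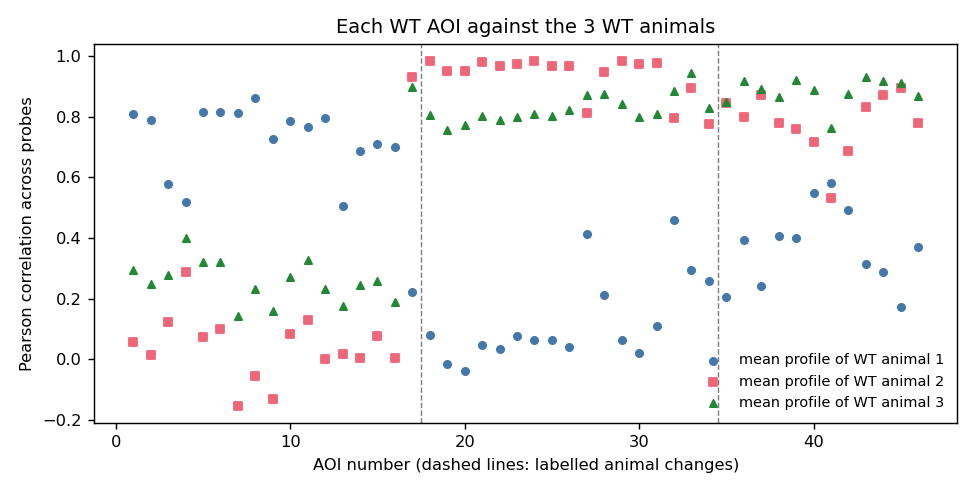
Pearson correlation across probes of each WT AOI (x axis, AOI number) with the mean profiles of WT animals 1, 2 and 3; dashed lines mark where the labelled animal changes. AOI 17 lies at 0.93 with WT animal 2 and 0.22 with its labelled animal 1.

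The question whether AOIs of an animal were more unlike each other in one genotype was addressed at equal depth. The median SD between AOIs over the 1000 most abundant probes was 0.644 ± 0.077 log2 units (SD, n = 3) in WT and 0.628 ± 0.043 (SD, n = 3) in 5XFAD. The difference of -0.0156 was not detectable against the spread between animals (two-sided exact permutation p = 0.9, smallest possible 0.1), and its sign turned without WT animal 1 and without 5XFAD animal 2. Thinning adds counting noise to these SDs. Without and with thinning the SD was 0.406 and 0.640 in WT animal 2, and 0.412 and 0.568 in WT animal 3. It was also higher with thinning in the other animals, except 5XFAD animal 2 (0.603 and 0.585). The share of counting noise was not measured, so the test cannot tell whether a genotype difference was hidden by it. In WT animal 1 the SD was 0.723, the highest of the 6 animals, and 0.614 on the same probes without AOI 17.

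**Figure D5:**
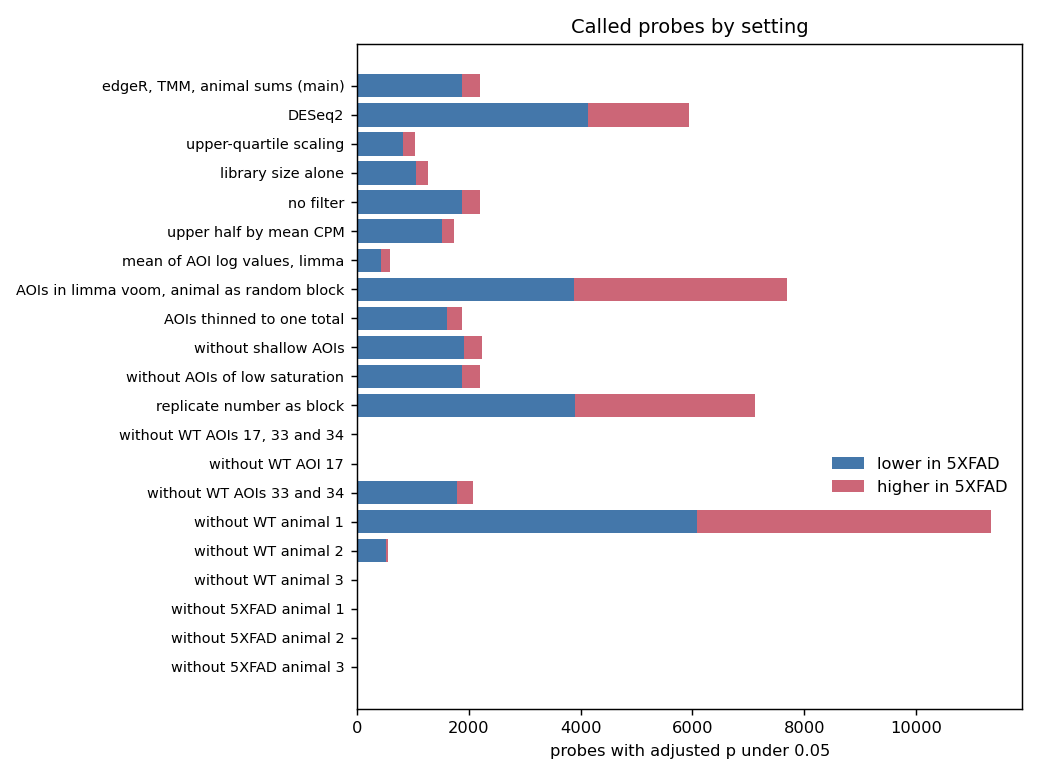
Number of probes with an adjusted p under 0.05 (x axis), split into lower and higher in 5XFAD, for each setting (y axis). The count is 2197 as tested on animal sums, 11336 without WT animal 1 and 0 in 6 settings that leave out AOIs or animals.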

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

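The removals of AOIs 17, 33 and 34, and that of the poorly saturated AOI for the saturation difference, were chosen after the data were seen, and all other alternatives before the data were examined. The fold changes of the 2197 called probes had the same sign under each alternative in which they were tested, but their number moved by over 1.5 times under 14 of 20 alternatives. For all called, higher and lower probes in turn, the counts were 5946, 1808 and 4138 with DESeq2, 1029, 204 and 825 with upper-quartile scaling, 1268, 208 and 1060 with library size alone, 588, 154 and 434 with AOI log means in limma, and 7698, 3824 and 3874 with AOIs in limma voom with the animal as a random block. They were 0, 0 and 0 in edgeR without WT AOI 17 (5405 at an unadjusted p under 0.05, 3883 called by DESeq2) and without AOIs 17, 33 and 34 (5354 and 3847), and 2083 in all without AOIs 33 and 34. Leaving out 1 animal gave ranges of 0 to 11336, 0 to 5250 and 0 to 6086, the highest without WT animal 1; where edgeR called 0 probes in these, the smallest adjusted p was 0.105 to 0.156. The cause was not tested. The loss of degrees of freedom was the same at 0 and 11336 calls. No filter, the upper part by CPM, thinning, and removal of shallow or poorly saturated AOIs gave 1732 to 2238 calls.

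With the animal number as a block the counts were 7127, 3228 and 3899. Whether the numbers pair the animals was not settled, and the test without the block was kept as set before the data were examined. Deviations of same-numbered animals from their genotype means correlated at 0.48, 0.50 and 0.05 over the 13303 probes with a mean log2 CPM over 5, and at 0.44, 0.46 and 0.11 over all tested probes, so that number 3 was under or over the limit of 0.1 depending on the probes used; this choice of probes was made with the blocked count known, and WT animal 3 deviated most like 5XFAD animal 2.

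Of the named probes, RTS0064820, RTS0064807 and RTS0067798 stayed called in 14 of 20 alternatives and RTS0064241 in 12, with no change of sign. Their edgeR, DESeq2 or limma adjusted p reached 0.156 at most, and 0.174 for RTS0064241. The depth difference kept its sign in all 7 alternatives and ranged from -0.544 to -0.158, the smallest without WT animal 2. The saturation difference turned to 0.355 points with medians over AOIs, was -0.186 without the poorly saturated AOI, and ranged from -2.33 to -0.0776 with 1 animal left out. The difference in spread turned to 0.0697 without thinning, 0.000469 with 3000 probes and 0.0179 without AOIs 17, 33 and 34, and ranged from -0.0533 to 0.0240 with 1 animal left out; the cause was not tested. The alternatives for gene lists and for negative control probes were not run, since the probes carry no names here. With the depths, spread and 3 animals per genotype simulated together, 6 of 67 changes of 1.5-fold were called.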

Other observations

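The tests of genotype, of 1 shared source and of the animal number in the labels were chosen after the results were seen; the tests of sequencing depth, of low depth by thinning, of splits of the animals and of the shared axis were fixed before theirs were seen.

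Probes that varied together between AOIs of 1 animal also varied together in the other animals. In 5XFAD animal 3, the first principal component of its 15 thinned AOIs held 30.8% of the variance over the 3000 most abundant probes, and the 50 probes with the highest loading ranged over 4.29 log2 units between AOIs in their mean level. These 50 probes had a mean pairwise correlation over AOIs of 0.65 in WT animal 1, 0.41 in WT animal 2, 0.66 in WT animal 3, 0.65 in 5XFAD animal 1 and 0.59 in 5XFAD animal 2. As an axis shared by the animals would require, in 5 of 5 other animals this exceeded all of 1000 random lists matched on mean level, whose highest value was 0.179. The lists were not matched on variability, and probes that vary little correlate little. The comparison therefore cannot tell whether other sets of variable probes would do the same. None of the 50 was called between genotypes (0 higher and 0 lower by edgeR). Their mean level was not even across animals, at 5.88 log2 units in WT animal 2 and 6.78 to 7.20 in the other 5 animals. An axis of tissue composition or brain region, which the labels do not record, may underlie the shared variation, and was not tested.

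WT animals 2 and 3 stood apart from WT animal 1 and from the 5XFAD animals. A difference in the number of counts is argued against as the cause. With every AOI thinned to 103170 counts, WT animal 2 correlated with the 5XFAD mean at 0.282, against 0.766 for the least alike pair of 5XFAD animals. It stayed below such a pair in all 100 resamplings of AOIs. Thinning keeps each AOI's ratio of signal to background, so a difference in background was not tested. The 1st percentile of probe CPM before TMM scaling was 10.88 and 10.67 in WT animals 2 and 3. It was 16.86 in WT animal 1 and 16.75 to 19.54 in the 5XFAD animals. Genotype as the whole cause cannot be decided by the tests run, which rest on 1 animal and carry no spread between animals. The quantity used was WT animal 1's correlation with WT animal 2 minus that with the 5XFAD mean. It was -0.372 on summed counts (95% interval over resampled AOIs -0.559 to 0.0616) and -0.386 with AOIs weighted equally (-0.461 to -0.209). Without AOIs 17, 33 and 34 it was -0.561 (-0.5808 to -0.4475), so that the whole interval lay below 0. That removal was chosen after seeing the data and takes out AOI 17, which resembled WT animal 2. Of the 17 AOIs of WT animal 1, 16 were nearer to the 5XFAD profile than to WT animal 2. A single source of extra signal mixed in at different shares cannot be told apart from other causes. Of 830 probes at least 4-fold higher in WT animal 2 than in 5XFAD, 52.3% had an excess in WT animal 3 within 1.5-fold of the median ratio of 0.837. This lay between the bounds of 50% and 80% set for it. The test did not cover the 302 probes at least 4-fold lower in WT animal 2 than in the 5XFAD mean. Differences in brain region, section or handling between animals stay open and untested.

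AOIs 17, 33 and 34, the last of their labelled animals, resembled the WT animal that follows in AOI order. On 200 probes chosen without these AOIs to separate the 2 animals concerned, with 0 at the labelled animal and 1 at the next, they lay at 0.895, 0.925 and 0.889, inside the range of the next animal and above that of the labelled one. AOIs 27 and 32 stayed in the choice of probes as AOIs of WT animal 2, unless they were the AOI measured. This can hold down the range of WT animal 2, so the separation of AOIs 33 and 34 may be partly built in. The thinning given next used the same choice. A low number of counts is argued against. AOIs 17 and 33 lay above the median total of all AOIs. When the other 15 AOIs of WT animal 2 were thinned to the 127984 counts of AOI 34, 0 reached the range of WT animal 3 in any of 20 thinnings (highest position 0.591, range from 0.684). Thinning does not change background, which was not tested. The thinning took the place of a comparison with shallower WT AOIs, all of which came from WT animal 1. For AOI 17 a wrong animal number in the label is a candidate explanation, with carry-over between neighbouring wells and a difference between areas not tested. For AOIs 33 and 34 it cannot be told apart from variation within WT animal 2, since AOIs 27 and 32 of that animal had larger gaps in correlation towards WT animal 3 (0.0577 and 0.0903) than AOIs 33 and 34 (0.0491 and 0.0544).

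For the number of called probes, the real grouping gave 2197 (314 higher and 1883 lower) and the highest of the other splits of the 6 animals into 3 and 3 gave 0, so that 1 of 10 splits reached the real value in each case. With 10 splits the share cannot fall below 0.1, which is too few for a share under 0.05. The contrast also rests on AOI 17 of WT animal 1, without which the real grouping gave 0 as well. A count of 0 does not mean that few probes differed. Settings in which edgeR called 0 probes had 4039 to 5405 probes at an unadjusted edgeR p under 0.05.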
